A study of Mus musculus with 50 samples.

How the data were processed

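Liver RNA from formalin-fixed, paraffin-embedded tissue of female B6C3F1 mice was hybridised by the authors to Agilent SurePrint G3 mouse expression arrays in a single colour (Cy3), after chemical labelling of cDNA. The 50 arrays covered 5 doses of furan (0 as corn oil vehicle, 1, 2, 4 and 8 mg/kg body weight per day, 21 days) and 2 times in formalin (18 h and 3 wk), with 5 arrays per group. RNA came from 1 section of 10 µm per 18 h sample and 2 sections per 3 wk sample. One field of the labels gives 18 h for all 50 samples, while the titles and source names give 3 wk for 25 of them; the titles were used. The treatment protocol names only 8 mg/kg, while the titles and the series design give all doses; these were used.

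Per the file headers, the scanner files hold intensity values from Agilent Feature Extraction 11.0.1.1: the processed signal is an intensity with background subtracted and spatial trend removed, not normalized between arrays, and the median spot and local background signals are intensities as scanned. The other deposited columns are 0 or 1 flags per spot, such as well above background. The deposited series matrix holds log2 values that were normalized between arrays by a method the labels do not state; its array medians lay between 7.93 and 8, and its Spearman correlation with the log2 signal was at least 0.883 on every array.

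Each array had 62976 spots, of which 59305 were not controls, for 55681 probes. Probes were matched to gene symbols through their accessions and the supplied RefSeq table, which gave 27235 probes a symbol, for 20660 symbols. Spots of 1 probe were averaged, leaving out outlier spots unless all were outliers. The median array had 51.9% of probes well above background, and 13948 probes were well above background on all arrays. Across all arrays 2 non-control spots were saturated and 0.26% of spots were outliers in the scanner's own tests. No 2 arrays were identical.

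The log2 processed signal of each array was centred on its 75th percentile over all non-control probes. Probes well above background on at least 4 of 5 arrays of a group were kept, and the kept probe with the highest mean over the 50 arrays stood for its gene; probes without a symbol counted as genes of their own. This left 29134 genes at 18 h, 22969 at 3 wk and 30233 over both. Linear models with slide as a block (8 slides, scanned on 5 days) were fitted in limma 3.58.1 under R 4.3.3 (the R package for reading the files was version 1.17.8), with moderated t tests and Benjamini-Hochberg adjustment at 0.05. Each dose was compared with vehicle in a fit of the 25 arrays of that time, which also gave a linear trend over dose. A fit of all 50 arrays gave the comparison of formalin times, averaged over dose groups, and the difference between times in the effect of 8 mg/kg/day. Residual degrees of freedom were 13, 13 and 33. A gene not well above background on any array of the lower group is given a bound in place of a fold change.

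Before the data were examined, 17 gene lists and 12 lists of cell type markers were fixed. They were tested with camera at an inter-gene correlation of 0.01 and then with the estimated correlation, where at least 4 members were measured. Genes named for 8 mg/kg/day and for the formalin times were the 12 largest rises and falls among called genes with a symbol for which every array of the higher group exceeded the mean of the other group; the other comparisons took 4 each way. Up to 4 members of each list with the smallest adjusted p and a set of anchor genes were also named. Members of a list are given with their standard error, and a list count adjusted over the list alone applies the Benjamini-Hochberg method within its members. No probe matched Gsta1, and no mitochondrially encoded gene was measured. Skeletal muscle markers had 3 measured members at each time, too few for a test, and 4 in the fit of both times (adjusted p = 0.97 between times). B and plasma cell markers had 2 after 3 wk and were not tested there.

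The methods were tested on simulated data drawn from the fitted models with normal noise of each gene's own spread, with known changes added. At 8 mg/kg/day after 18 h, 62% of 100 genes changed by 1 on the log2 scale and 97% of 100 changed by 2 were recovered; after 3 wk the shares were 6% and 72%. Each simulation had 6 false calls, and the changed list was called while 0 of 20 unchanged lists were. Noise was drawn independently for each gene and the lists were random genes. False calls that arise from correlation between genes were therefore not simulated.

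Alternatives planned before the data were examined were quantile normalization, the 75th percentile over probes detected on all arrays, normexp background correction with an offset of 50, no filter, no slide block, slide as a random block, scan date as a block, all kept probes, the series matrix values, all 50 arrays in 1 fit, replicate number as a block, vehicle arrays only, another detection flag, an estimated correlation and leaving out each array. The normexp correction used median spot signals, in place of mean signals, which were not used here. Leaving out slides 7 and 8, choosing the probe on the 18 h arrays, a signal covariate and leaving out arrays with high pancreatic marker scores were chosen after seeing the data. Counts were compared with those of up to 100 other splits of the same arrays. Shared replicate numbers between formalin times were not treated as the same animal in the reported fits, because the labels do not say so. The chance draws for the correlation between times are an exception: they shuffled both times together by replicate number.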

Results

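Furan is a small volatile compound that forms in heated food and damages the rodent liver, where it is oxidised mainly by the cytochrome P450 enzyme Cyp2e1. Liver transcripts were measured in female B6C3F1 mice, a hybrid strain used in toxicology studies, that were given corn oil vehicle or furan at 1, 2, 4 or 8 mg/kg body weight per day by gavage for 21 days, with tissue taken 4 h after the last dose. Each liver sample had been fixed in formalin and embedded in paraffin, and the time in formalin was either 18 h or 3 wk. The 50 arrays formed 10 groups of 5, one for each combination of dose and time in formalin. The 5 replicates per group, described by the submitters as biological, limited the precision of every comparison.

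RNA integrity numbers lay between 1.3 and 2.4, so all RNA was strongly degraded. On the arrays of 18 h in formalin, 57.4% ± 4.44 (SD, n = 25) of probes lay well above background, with a range from 47.3% to 65.2%. After 3 wk the share was 45.4% ± 5.01 (SD, n = 25), with a range from 33.1% to 54.4%. The difference of -12 percentage points gave p = 1e-05 in a two-sided permutation test with 100000 resamples, the smallest value these can give, and the share was lower after 3 wk on each of the 8 slides. The 75th percentile of the signal was 514 ± 174 after 18 h and 192 ± 69.3 after 3 wk (SD, n = 25 each). Median residual SD of a gene was 0.308 on the log2 scale after 18 h and 0.491 after 3 wk.

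**Figure D1:**
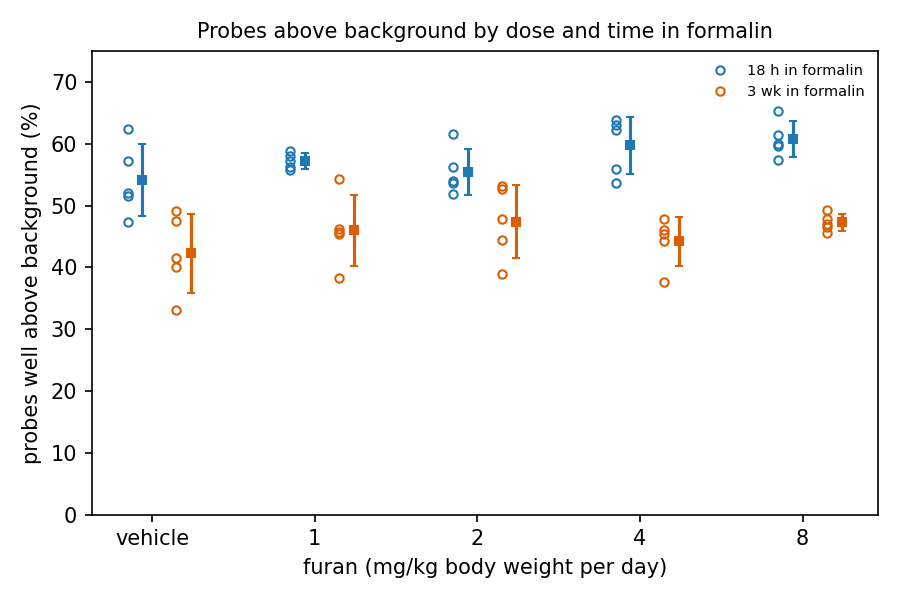
Share of probes well above background (%, vertical axis) on each array by dose and time in formalin; open circles are arrays, squares with bars the mean ± SD of 5 arrays. Means lay between 54.1% and 60.7% after 18 h and between 42.3% and 47.4% after 3 wk.

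The first comparison asked what 8 mg/kg/day furan did to liver transcripts in tissue fixed for 18 h. Targets of p53, the transcription factor activated by DNA damage, rose most: Phlda3, a p53-induced inhibitor of Akt signalling, was 18.1-fold higher (log2 fold change 4.18 ± 0.25 (SE), adjusted p = 1.08e-07), and the death receptor Tnfrsf10b, not well above background on any vehicle array, was at least 9.5-fold higher, a bound computed by raising each vehicle array to its lowest well above background value where it lay below that. Antioxidant and glutathione genes, mitotic genes, heat shock proteins, immediate early genes and genes of the endoplasmic reticulum stress response also rose as groups at the fixed correlation of camera, and none of these 5 groups passed with an estimated correlation. Among the falls were the sterol-metabolising enzymes Cyp46a1, Hsd17b6 and Cyp8b1, the pericentral genes Oat and Cyp1a2, and Spp1, which encodes osteopontin. In all, 10173 of 29134 genes tested passed limma at a Benjamini-Hochberg adjusted 0.05. Of these, 5703 were higher and 4470 lower, and 1829 and 931 of them changed 2-fold or more. A gene symbol was known for 14044 of the genes tested and 5974 of those called, and the rest were single probes without a symbol. Probes of 1 gene often disagreed: of 931 genes with 2 or more called probes, 383 had calls both ways.

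Of 20 measured p53 targets, 18 rose and 2 did not pass the test. The zinc finger gene Zmat3 rose by 3.15 ± 0.27 on the log2 scale, the stress cytokine Gdf15 by 2.95 ± 0.26 and Mdm2, the ubiquitin ligase that degrades p53, by 1.91 ± 0.19 (SE, 5 arrays per group). Adjusted over the list alone the count was also 18, and the list rose in camera (adjusted p = 8.9e-13, and adjusted p = 0.048 with an estimated correlation). For Cdkn1a, the cell cycle inhibitor induced by p53, the probe used gave 0.20 ± 0.30 (adjusted p = 0.643). A second probe of the same gene, not used because it was the dimmer of the pair over all 50 arrays, gave 2.83 ± 0.18. After 18 h this second probe was the brighter, with a vehicle mean of -1.03 against -2.98, and was well above background on all 5 vehicle and 5 dosed arrays. The probe used was so on 4 vehicle and 2 dosed arrays. Ccng1, another p53 target, rose by 0.90 ± 0.25 (adjusted p = 0.0121).

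Among 19 genes of the NRF2 response, which answers oxidants and electrophiles, 11 rose and 1 fell; adjusted over the list alone, 13 rose and 2 fell. The glutathione transferase Gsta2 rose by 2.00 ± 0.24, the carbonyl reductase Cbr3 by 1.92 ± 0.25, the epoxide hydrolase Ephx1 by 1.59 ± 0.19 and the sulfiredoxin Srxn1 by 1.48 ± 0.23. Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, rose by 1.07 ± 0.23 (adjusted p = 0.00254), and Hmox1 by 0.88 ± 0.26 (adjusted p = 0.0164). Nqo1 gave 0.78 ± 0.32 (adjusted p = 0.07) and Gstm3 0.62 ± 0.27 (adjusted p = 0.084), and neither passed. The list had an adjusted p of 0.00019, which became an adjusted p = 0.27 with an estimated correlation.

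Cell cycle genes rose in 14 of 18 cases, the same count as adjusted over the list alone. The mitotic kinase Cdk1 rose by 2.30 ± 0.36, Cdc20 by 1.85 ± 0.33, Birc5 by 1.82 ± 0.34 and Aurka by 1.67 ± 0.24, while the proliferation marker Mki67 gave 0.44 ± 0.38 (adjusted p = 0.392). Of 10 heat shock proteins, 8 rose, and 10 adjusted over the list alone, with Hspa4l at 2.17 ± 0.34 and Hspb1 at 2.00 ± 0.29. Among 12 immediate early genes 8 rose, and 8 rose and 1 fell adjusted over the list alone; Jun, a subunit of the AP-1 transcription factor, rose by 2.78 ± 0.22. Of 18 genes of the endoplasmic reticulum and integrated stress response, 10 rose and 1 fell, also when adjusted over the list alone, with the hormone Fgf21 at 2.71 ± 0.24 and Ddit4 at 1.66 ± 0.23. Camera gave these lists adjusted p = 6.1e-05, 3.8e-05, 0.009 and 0.0073 in that order, and with an estimated correlation adjusted p = 0.27, 0.27, 0.11 and 0.27.

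Cholesterol biosynthesis had 6 rises among 17 genes, and 6 adjusted over the list alone, including the squalene epoxidase Sqle at 1.53 ± 0.23 and Hmgcs1 at 1.14 ± 0.18 (list adjusted p = 0.033; adjusted p = 0.56 with an estimated correlation). Ribosomal protein genes had 11 rises and 2 falls among 20, and 13 and 2 adjusted over the list alone, with Rpl4 at 1.00 ± 0.22 (list adjusted p = 0.0091; adjusted p = 0.78 with an estimated correlation). Rpl27 also rose, by 0.90 ± 0.19, but a second probe of it gave -0.19.

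No list fell as a whole, although single genes of hepatocyte metabolism did. Of 19 cytochrome P450 genes 8 fell and 2 rose (adjusted p = 0.44): Cyp1a2 changed by -1.02 ± 0.17, Cyp2b9 by -0.93 ± 0.20 and Cyp2d9 by -0.93 ± 0.23, while Cyp2e1 gave -0.27 ± 0.14 (adjusted p = 0.14). Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis, changed by -1.68 ± 0.35 and Cyp27a1 by -0.75 ± 0.17, in a list of 14 with 3 rises and 2 falls (adjusted p = 0.91). Among 16 hepatocyte plasma protein and urea cycle genes 3 fell and 1 rose (adjusted p = 0.19), and both Cps1, the entry enzyme of the urea cycle, and Pck1, an enzyme of gluconeogenesis, changed by -1.08. Alb gave -0.18 ± 0.21 (adjusted p = 0.533) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, -0.32 ± 0.47 (adjusted p = 0.631).

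Inflammatory genes moved in both directions. Cxcl10, an interferon-induced chemokine, rose by 3.76 ± 0.61, whereas the monocyte chemoattractant Ccl2 changed by -1.42 ± 0.26 and Saa1 gave 0.51 ± 0.83 (adjusted p = 0.67); the list of 15 had 3 rises and 2 falls (adjusted p = 0.82). Of the cell type markers, Sox9 rose at least 1.49-fold and Spp1 changed by -1.71 ± 0.20 in the cholangiocyte list of 8. Endothelial markers had 4 falls and 1 rise among 11, with Fcgr2b at -1.16 ± 0.16 and Cdh5 at 1.67 ± 0.53. Pericentral hepatocyte markers had 3 falls and 2 rises among 10, with Oat at -1.27 ± 0.19 and Lgr5 at 1.00 ± 0.26, and Glul at 0.34 ± 0.18 (adjusted p = 0.145). None of the 11 cell type lists tested passed camera. Nor did PPAR alpha targets (2 rises among 16, adjusted p = 0.44), lipogenesis (0 calls among 10, adjusted p = 0.91), circadian clock genes (1 rise and 1 fall among 12, adjusted p = 0.88) or extracellular matrix genes (3 rises and 3 falls among 15, adjusted p = 0.91). The largest other rises, Gm3776 at 3.78 ± 0.49, Sebox at 3.34 ± 0.55 and Insc at 3.19 ± 0.53, and the largest falls, Hectd2 at -2.32 ± 0.21, Cyp46a1 at -2.21 ± 0.23 and Hsd17b6 at -2.18 ± 0.24, were named by a rule that asks each array of the higher group to exceed the mean of the other. Dppa5a, Chrna9, Gtse1 and Gdf9 were not well above background on any vehicle array and were at least 6.37-fold, 3.72-fold, 3.88-fold and 3.89-fold higher. Spink1, a trypsin inhibitor made by pancreatic acinar cells, was also called. No bound is given, because its array of replicate 45 (2.05) lay far from the other 4 (-2.45 to -1.63). Those 4 still lay above every vehicle array (-5.66 to -4.17). The score of 6 pancreatic acinar markers was 5.16 on the array of replicate 45.

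**Figure D2:**
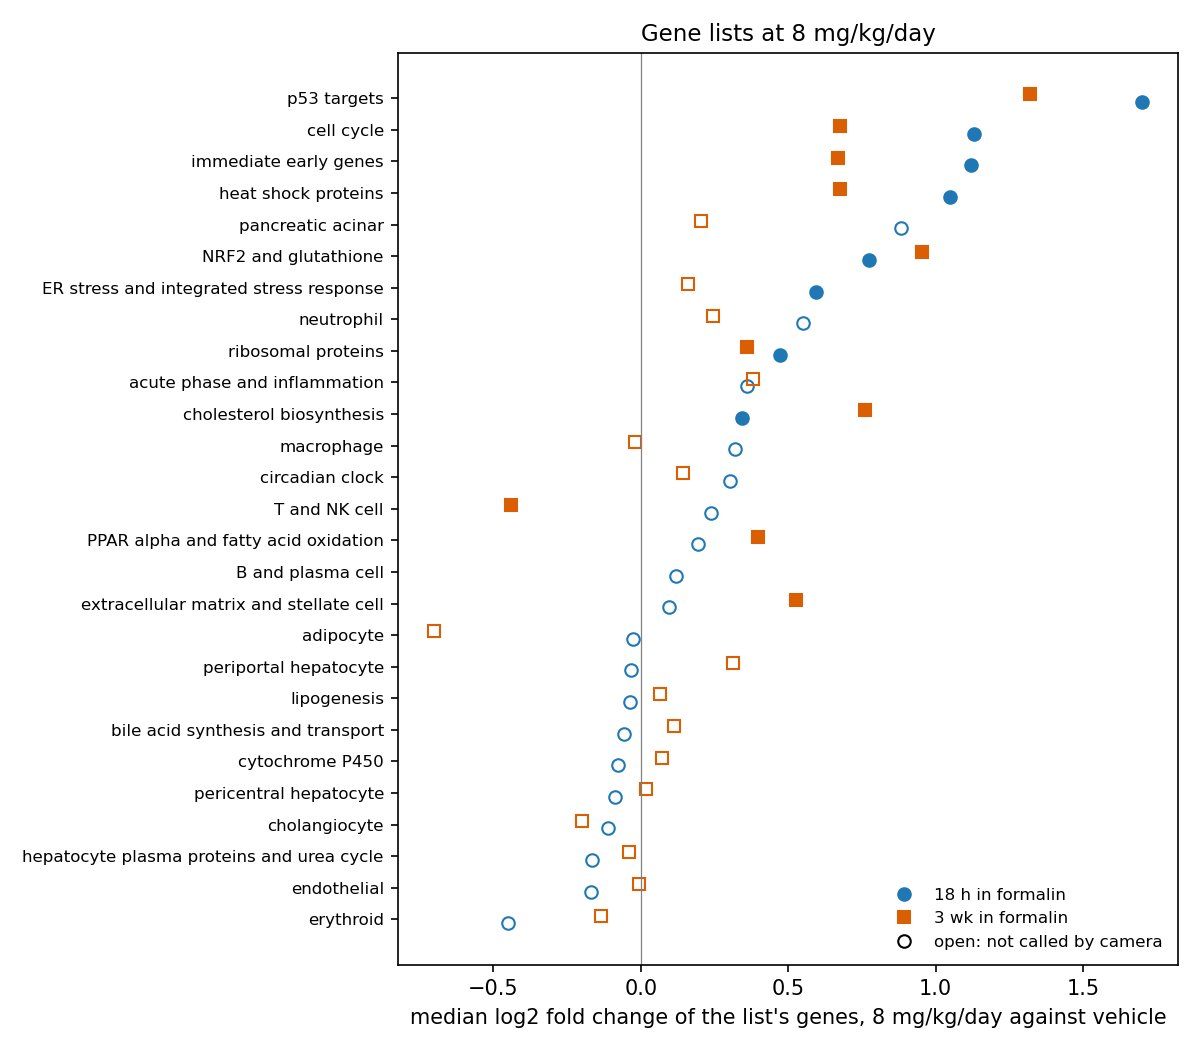
Median log2 fold change of each gene list and marker list with 4 or more measured members (horizontal axis) at 8 mg/kg/day against vehicle, for 18 h and 3 wk in formalin; filled symbols passed camera at an adjusted 0.05 and open symbols did not. The p53 list stood at 1.7 after 18 h and 1.32 after 3 wk, and the NRF2 list at 0.775 and 0.953.

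Within the 3 slides that held both an 8 mg/kg/day and a vehicle array of 18 h, the median of the p53 list was 1.19, 1.85 and 1.73 and that of the NRF2 list 0.3, 0.698 and 0.764. Signal moved with this dose: 54.1% of probes were well above background in vehicle and 60.7% at 8 mg/kg/day, and the 75th percentile signal was 479 and 616. With that signal as a covariate, chosen after seeing the data, 8189 genes were called, 8007 of them among the 10173. Scaling on the probes detected on all arrays moved the median of all genes by -0.19 and turned the split to 3890 higher and 6818 lower, and leaving out vehicle replicate 2 lowered the count to 6753.

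After 3 wk in formalin the same dose gave 61 calls among 22969 genes, 39 higher and 22 lower, all changed 2-fold or more. Genes of the p53 and glutathione lists were again among the rises, with Phlda3 at 3.38 ± 0.43 (SE, adjusted p = 0.00193), Tnfrsf10b at 3.09 ± 0.48, Gdf15 at 2.43 ± 0.36 and Gsta2 at 2.59 ± 0.42 (adjusted p = 0.00845). The rises also held Gm3776 at 5.08 ± 0.72, the macrophage elastase Mmp12 at 4.45 ± 0.53, the fetal plasma protein Afp at 2.76 ± 0.29 (adjusted p = 0.000446), Jun at 2.68 ± 0.40 and the insulin-like growth factor binding protein Igfbp1 at 2.32 ± 0.39.

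Of 14 measured p53 targets 4 rose, and 9 rose and 1 fell adjusted over the list alone (list adjusted p = 2.8e-07; adjusted p = 0.025 with an estimated correlation). Mdm2 gave 1.94 ± 0.46 (adjusted p = 0.072). The probe used for Cdkn1a gave -1.22 ± 0.36 (adjusted p = 0.133), and the other probe of that gene, well above background on 0 of 5 vehicle arrays and 5 of 5 dosed arrays, moved the other way. Of 17 NRF2 genes 3 rose, and 10 adjusted over the list alone (list adjusted p = 1e-07; adjusted p = 0.025 with an estimated correlation). Osgin1 rose by 1.82 ± 0.32 and Srxn1 by 1.41 ± 0.29, while Nqo1 gave 2.18 ± 0.63 (adjusted p = 0.123), Hmox1 1.66 ± 0.46 (adjusted p = 0.109) and Gclc 1.25 ± 0.45 (adjusted p = 0.197).

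Of 17 cholesterol biosynthesis genes none passed over all genes, and 10 rose adjusted over the list alone; Cyp51, the lanosterol demethylase, gave 1.99 ± 0.42 (adjusted p = 0.0579), and the list rose with an adjusted p of 2.8e-07 (adjusted p = 0.074 with an estimated correlation). Extracellular matrix genes had 0 calls among 14, also adjusted over the list alone, and a list adjusted p of 0.0024 (adjusted p = 0.074 with an estimated correlation). Heat shock proteins, with Hspb1 at 2.11 ± 0.32, immediate early genes, cell cycle genes, PPAR alpha targets and ribosomal protein genes rose as lists with adjusted p = 0.00078, 0.0044, 0.0044, 0.013 and 0.01; with an estimated correlation these gave adjusted p = 0.099, 0.21, 0.3, 0.49 and 0.48. Adjusted over the list alone they had 2, 3, 3, 1 and 0 rises. T and NK cell markers fell as a list of 7 (adjusted p = 0.025; adjusted p = 0.22 with an estimated correlation), with 3 falls adjusted over the list alone and Nkg7 at -1.07 ± 0.30 (adjusted p = 0.115). Among 19 cytochrome P450 genes there were 0 calls (list adjusted p = 0.95), and Cyp2e1 gave -0.68 ± 0.22 (adjusted p = 0.153) and Cyp1a2 0.31 ± 0.34 (adjusted p = 0.69). Trem2, a macrophage receptor, gave 2.02 ± 0.43 (adjusted p = 0.0581), but the macrophage list had 3 of 8 markers above 0 and did not pass (adjusted p = 0.68), with Adgre1 at -0.40 and Cd5l at -0.46, neither past the test. The largest falls were Olfr1316, at least 1.44-fold lower, Prkg1 at -2.12 ± 0.40, Mc5r at -2.08 ± 0.39 and Hectd2 at -1.69 ± 0.31. Ccng1, Spp1 and Krt19 were not tested at this time, because too few arrays had them well above background.

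Within the 2 slides that held both arms after 3 wk, the p53 median was 1.07 and 0.848 and the NRF2 median 0.486 and 0.841. The count moved with single arrays, to 16, 26, 30 and 33 without vehicle replicate 1, 2, 4 or 6, to 39, 34, 21 and 25 without 8 mg/kg/day replicate 41, 42, 43 or 44 and to 222 without replicate 45. It was 0 in limma without slides 7 and 8 (3262 at an unadjusted p under 0.05), which left 2 dosed arrays, and quantile scaling split it as 66 higher and 106 lower.

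Agreement between the fixation times was then measured across genes. Over 21802 genes tested in both, the log2 fold changes of 8 mg/kg/day correlated at r = 0.176 across genes, which are not independent replicates. Unchanged groups gave r between -0.295 and 0.367 in 100 draws, which kept arrays with the same replicate number together. The covariance was 0.0595, against a mean of 0.00487 and a highest value of 0.0741 by chance, so neither measure lay beyond chance in the reported setting, where the draws were made. Of 52 shared genes called after 3 wk, 36 were also called after 18 h and 34 had the same sign, with 32 higher in both where independent lists would give 7.8, and 2 lower in both where they would give 2.43. The value of r was -0.00263 and 0.408 without vehicle replicate 1 or 3 of 3 wk and 0.0862 without 8 mg/kg/day replicate 42 of 3 wk. It was 0.393 without slide as a block, 0.422 without slides 7 and 8 and 0.0936 with the series matrix values.

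The test of the difference itself called 1881 of 30233 genes, with 978 more positive after 3 wk and 903 more negative. Of genes tested at both times, Fcgr2b differed by 1.69 ± 0.34 (adjusted p = 0.0037), Ccl2 by 1.73 ± 0.43 (adjusted p = 0.0153) and Cyp1a2 by 1.18 ± 0.34 (adjusted p = 0.0342), all falls of the 18 h tissue, and the apoptosis gene Bax by -2.18 ± 0.38 (adjusted p = 0.00118). The p53 list was lower after 3 wk in this test, with 3 of 20 genes past the threshold (adjusted p = 0.006; adjusted p = 0.46 with an estimated correlation); only 14 of the 20 were above background on enough arrays to be tested after 3 wk. Mdm2 gave -0.10 ± 0.48 (adjusted p = 0.937), Gsta2 0.68 ± 0.50 (adjusted p = 0.457) and Phlda3, named after its values were seen, -0.74 (adjusted p = 0.341). The count was 1200 and 1214 without vehicle replicate 1 or 6 of 18 h, 1020 without vehicle replicate 3 of 3 wk, and 1206 and 968 without 8 mg/kg/day replicate 43 or 44 of 3 wk, and it was 117 without slides 7 and 8. With replicate number as a block with slide the count was 0 in limma, though the labels do not say that shared numbers mean the same animal.

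At 4 mg/kg/day after 18 h, p53 targets rose again: Phlda3 by 2.31 ± 0.23 (adjusted p = 0.00039), Gdf15 by 1.54 ± 0.24, the nuclease Aen by 1.06 ± 0.16 and Mdm2 by 0.81 ± 0.18 (adjusted p = 0.0393), with Tnfrsf10b at least 2.37-fold higher. Of 20 p53 targets 7 rose, and 12 adjusted over the list alone (list adjusted p = 6.6e-13; adjusted p = 0.046 with an estimated correlation). The NRF2 list had 2 rises among 19, Gpx2 at 0.84 ± 0.19 and Ephx1 at 0.78 ± 0.17, and did not pass as a list (adjusted p = 0.73). Spp1 changed by -1.07 ± 0.18 (adjusted p = 0.0125), Fndc3a by -1.53 ± 0.19 and Psmd14, a proteasome subunit, by -1.50 ± 0.26. Heat shock proteins rose as a list (adjusted p = 0.00014; adjusted p = 0.4 with an estimated correlation) with none of 10 past the threshold over all genes and 4 adjusted over the list alone.

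The count at this dose was 282 genes, 166 higher and 116 lower. Of these, 152 were also higher and 115 also lower at 8 mg/kg/day and none went the other way, where independent lists would share 32.5 and 17.8. Both comparisons used the same vehicle arrays. Unchanged groups against them shared 0.08 calls on average and at most 7. Splitting the vehicle arrays left 40.9 shared, where 4 mg/kg/day had 100 calls and 8 mg/kg/day 6180. The correlation of the log2 fold changes of 4 and 8 mg/kg/day was 0.746, against 0.497 by chance and 0.405 with split controls, and the covariance was 0.162 against 0.0382. The count was 142 and 47 without vehicle replicate 1 or 6, and 509, 180, 43 and 87 without 4 mg/kg/day replicate 31, 33, 35 or 36. Without slide as a block it was 52, and quantile scaling split it as 132 higher and 145 lower.

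After 3 wk, 4 mg/kg/day gave 122 calls, 17 higher and 105 lower. Mmp12 rose by 2.90 ± 0.50 and Phlda3 by 2.16 ± 0.41 (adjusted p = 0.0304), and Trappc13 was at least 1.57-fold higher, while Kifc3, a kinesin, was at least 3.92-fold lower, Pate5 changed by -2.42 ± 0.46 and Txndc8 was at least 1.83-fold lower. The probe used for Cdkn1a changed by -1.60 ± 0.34 (adjusted p = 0.0449), and the other probe, not well above background on any vehicle array, moved the other way. The p53, NRF2, heat shock, cytochrome P450, cholesterol and ribosomal lists rose and T and NK cell markers fell in camera, with adjusted p between 0.0059 and 0.034, and none of the 7 passed with an estimated correlation (lowest adjusted p = 0.4). Of the 122 genes, 10 were also higher and 5 also lower at 8 mg/kg/day, against 0.0289 and 0.101 for independent lists. Unchanged groups shared 0.72 calls on average but up to 72. Split controls left 0.6 shared, where 4 mg/kg/day had 123 calls and 8 mg/kg/day 95.4. The log2 fold changes of both doses correlated at 0.647, against 0.454 by chance and 0.185 with split controls, with a covariance of 0.216 against 0.0818. The count was 10, 45, 361, 6 and 6 without vehicle replicate 1, 2, 3, 4 or 6, and 24, 64, 1 and 23 without 4 mg/kg/day replicate 31, 33, 34 or 35. Leaving out slides 7 and 8 left 0 in limma, with 4792 at an unadjusted p under 0.05.

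At 1 and 2 mg/kg/day no gene passed limma at either time. Unadjusted p under 0.05 was reached by 773 and 1471 genes after 18 h, where chance gives 1457, and by 1037 and 2440 after 3 wk, where chance gives 1148. Among p53 targets at 2 mg/kg/day, Gdf15 gave 0.96 ± 0.25 (adjusted p = 0.729) and Zmat3 0.91 ± 0.27 (adjusted p = 0.864) after 18 h, and Aen 1.00 ± 0.29 (adjusted p = 0.412) and Phlda3 1.00 ± 0.39 (adjusted p = 0.435) after 3 wk. At 1 mg/kg/day after 3 wk Mdm2 gave 1.24 ± 0.46 (adjusted p = 0.88). As lists, p53 targets, cell cycle genes and cholesterol biosynthesis rose at 2 mg/kg/day after 18 h (adjusted p = 1.6e-08, 1.4e-06 and 6.2e-08), and with an estimated correlation gave adjusted p = 0.095, 0.2 and 0.095; adjusted over the list alone they had 7, 1 and 5 rises. Acute phase genes (adjusted p = 1.7e-05), endoplasmic reticulum stress and heat shock genes (0.0025 each), neutrophil markers (0.033), immediate early genes (0.047) and pancreatic acinar markers (0.047) also rose there. In that group replicate 22 had a pancreatic score of 2.9, with the next at 0.182. Its replicates 24 and 25 had acute phase scores of 2.18 and 1.19, with the others from 0.0607 to 0.132, and replicate 24 a macrophage score of 1.79, with the others from -0.345 to -0.0595. At 1 mg/kg/day after 18 h cholesterol biosynthesis (adjusted p = 4.4e-06) and pancreatic acinar markers (0.011) rose. In the pancreatic score of that group replicate 15 stood at 2.69 and the next at 0.146. After 3 wk cholesterol biosynthesis rose at 1 and 2 mg/kg/day (adjusted p = 1.2e-05 and 0.001) and acute phase genes at 2 mg/kg/day (0.03). In the acute phase score of the latter group replicates 24 and 25 stood at 1.87 and 1.52 and the others from -0.0366 to 0.212, and replicate 24 had a macrophage score of 1.34, with the others from -0.425 to 0.208. Gsta2 gave -1.11 ± 0.23 (adjusted p = 0.49) at 2 mg/kg/day after 18 h. No list passed with an estimated correlation at 1 or 2 mg/kg/day, and list counts at these doses were not compared with other splits.

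Across all 5 doses after 18 h, 12154 genes followed a linear trend, 6720 upward and 5434 downward. Phlda3 rose by 0.54 ± 0.03 log2 units per mg/kg/day (adjusted p = 1.83e-09), Gsta2 by 0.30 ± 0.05 and Mdm2 by 0.24 ± 0.02, whereas Hsd17b6 changed by -0.29 ± 0.03, Cyp46a1 by -0.28 ± 0.03, Spp1 by -0.21 ± 0.02 and Cyp1a2 by -0.13 ± 0.02. Of 20 p53 targets 18 rose (list adjusted p = 2.5e-12; adjusted p = 0.025 with an estimated correlation). After 3 wk 460 genes followed a trend, 187 upward and 273 downward. Gm3776 rose by 0.64 ± 0.07, Mmp12 by 0.55 ± 0.06, Phlda3 by 0.42 ± 0.05, Gsta2 by 0.31 ± 0.04 and Nqo1 by 0.28 ± 0.07 (adjusted p = 0.0369). Among 17 NRF2 genes 7 rose, among 14 p53 targets 6 rose and among 14 extracellular matrix genes 1 rose, and these lists held with an estimated correlation (adjusted p = 0.0037, 0.0034 and 0.033). The 3 wk count moved to 43 without 8 mg/kg/day replicate 43 and to 11 without slides 7 and 8, and scaling on the detected probes split the 18 h trend as 4803 upward and 8013 downward.

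**Figure D3:**
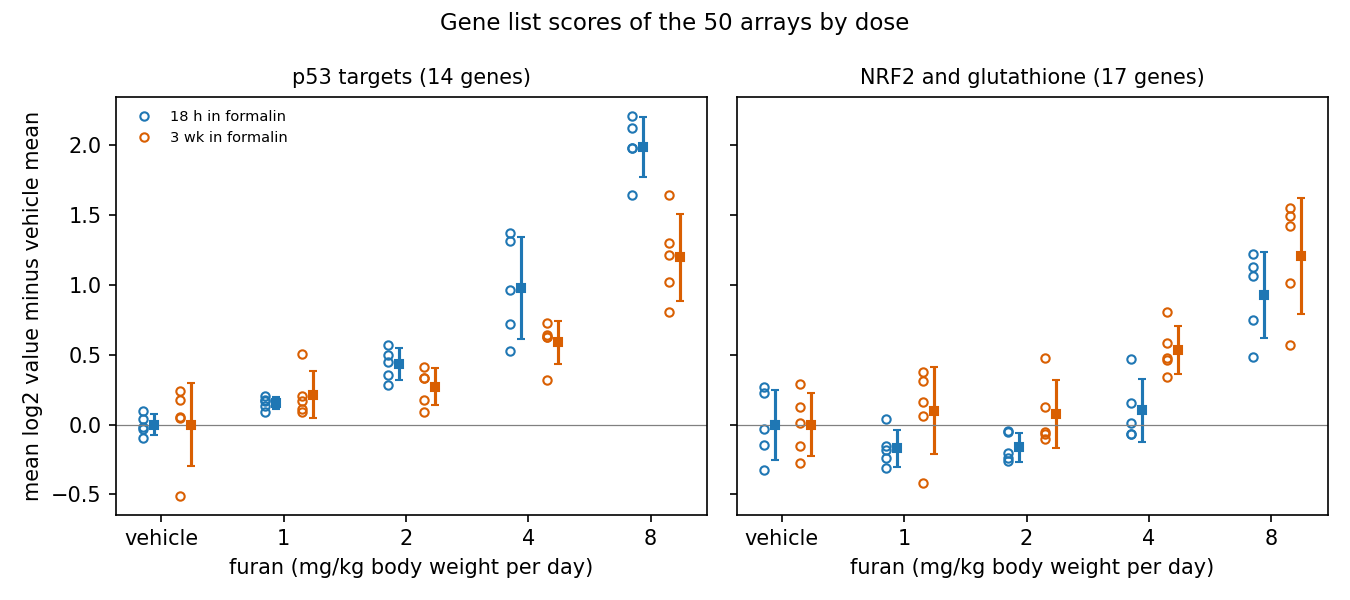
Mean log2 level of the p53 and NRF2 genes measured at both times, relative to the vehicle mean (vertical axis), on each array by dose in mg/kg/day; open circles are arrays, squares with bars the mean ± SD of 5 arrays. At 8 mg/kg/day the p53 score was 1.99 ± 0.217 after 18 h and 1.2 ± 0.313 after 3 wk, and the NRF2 score 0.927 ± 0.307 and 1.21 ± 0.416.

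The comparison of 3 wk with 18 h in formalin, averaged over the 5 doses, asked how fixation time altered the measured profile. It reached 24424 of 30233 genes, 12994 higher and 11430 lower after 3 wk relative to each array's 75th percentile, of which 7647 and 6537 changed 2-fold or more. Nfya, a subunit of the CCAAT-binding factor NF-Y, was higher by 6.75 ± 0.17 (adjusted p = 5.43e-30), and Gal3st3 by 6.37 ± 0.21. Aldh18a1, Fam229a and Kir3dl1 were not well above background on any 18 h array and were at least 13-fold, 14.8-fold and 12.9-fold higher. Falls included Nipsnap2 at -5.67 ± 0.23, Tubb2a at -5.19 ± 0.26, the pyruvate kinase Pklr at -4.51 ± 0.16 and the proteasome subunit Psma1 at -4.85 ± 0.21, while the mitochondrial ADP/ATP carrier Slc25a5 was at least 11.5-fold lower and Cops4 at least 10.9-fold lower.

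Genes of most lists moved both ways. No list passed camera among 28 tested: the NRF2 list had 10 higher and 7 lower of 19, and the p53 list 8 higher and 10 lower of 20 (adjusted p = 0.97 for both). Gdf15 was higher by 2.73 ± 0.13 after 3 wk while Mdm2 changed by -2.15 ± 0.15, and Alb was higher by 1.72 ± 0.10 and Trf by 2.63 ± 0.09 while Cyp1a2 changed by -1.96 ± 0.11. Hspb1 was higher by 2.59 ± 0.12. The sign differed between probes of Cdkn1a, with 3.80 ± 0.16 for the probe used and -2.47 for the other. Within each slide, between 92.8% and 97.8% of the called genes had the sign of the fit. This is no independent test, because the genes were called on the same arrays. The split of calls moved to 17800 higher and 8631 lower with another background correction, and the median of all genes by 0.28. RNA of the 3 wk samples came from 2 sections in place of 1, so time in formalin and the amount of tissue could not be told apart, and the labels do not say whether both times sampled the same animals.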

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

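Of the tests in this part, those on a technical axis shared with formalin time, on different annotated transcripts, on the number of calls after 3 wk and on the pancreatic markers (pancreatic tissue and a furan effect) were chosen only after the result was seen, as was leaving out slides 7 and 8 or the arrays with high pancreatic scores.

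The 10 groups of 5 arrays were examined on 5 measures for single arrays far from the rest, and 7 of these 50 sets had one, where chance gives about 1 in 20, or 2.5. The p53 score was low at -0.508 in vehicle replicate 1 of 3 wk, high at 0.504 in 1 mg/kg/day replicate 14 of 3 wk and low at 0.316 in 4 mg/kg/day replicate 35 of 3 wk. The score of 6 pancreatic acinar markers was high in 4 arrays: 2.69 in 1 mg/kg/day replicate 15 of 18 h, 2.9 in 2 mg/kg/day replicate 22 of 18 h, 5.16 in 8 mg/kg/day replicate 45 of 18 h and 1.89 in 4 mg/kg/day replicate 31 of 3 wk.

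In 8 mg/kg/day replicate 45 of 18 h, a candidate source of this signal is pancreatic tissue in the sample. All 6 measured markers lay more than 2 log2 units above the highest other array of the group: Ctrb1 by 5.23, Cpa1 by 4.79, Prss2 by 5.98, Pnlip by 4.63, Cela1 by 4.28 and Amy2a5 by 3.58. On that array the Ctrb1 and Cpa1 probes read 7.36 and 6.05 log2 units above the 75th percentile. A furan effect is argued against, because the highest score of the 4 other arrays was -0.03 relative to the vehicle mean. Without the 3 arrays of 18 h that scored over 1, the 8 mg/kg/day comparison had 6990 calls, of which 6680 were among the 10173.

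The effect of 8 mg/kg/day differed between formalin times in 1881 genes by a test of the difference itself, and in 117 without slides 7 and 8, which left 2 dosed arrays of 3 wk. With replicate number as a block with slide that count was 0. The genes named, as 3 wk minus 18 h, were Fitm1 at 3.73, Olfr132 at 3.16, Psmd14 at 2.73 and Acer2 at 2.70, and in the other direction Pnma2 at -3.66, Spink1 at -3.86, Ank at -3.90 and Insc at -4.02. Too few arrays had Olfr132 above background after 18 h, or Psmd14, Spink1, Ank and Insc after 3 wk, for a test at that time, so their differences set a change against background signal and give no size or rank. Fitm1 changed by -1.29 after 18 h and 2.59 after 3 wk. Spink1 in the 18 h tissue includes the array with the pancreatic signal, but the other dosed arrays (-2.45 to -1.63) also lay above vehicle (-5.66 to -4.17).

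Calls at 8 mg/kg/day were far fewer after 3 wk than after 18 h in the separate fits of each time. With all 50 arrays in 1 fit, where both times share the spread and slide terms, the counts were 5400 after 18 h and 1438 after 3 wk. The size of the gap thus depended on the fit. In the separate fits, 8126 and 52 of the 21802 genes tested at both times were called, a ratio of 156. This argues against fewer genes above background as the whole cause. Larger spread after 3 wk can be a large part of the gap. In the simulation, changes of 1 on the log2 scale were recovered in 62% of genes after 18 h and 6% after 3 wk. For changes of 2 the shares were 97% and 72%. As the only cause, larger spread would leave the changes of equal size. Yet the slope of the 3 wk on the 18 h change, corrected for error, was 0.192. It ranged from -0.00296 to 0.514 with vehicle replicate 1 or 3 of 3 wk left out. For 14 p53 targets the median was 1.88 after 18 h and 1.32 after 3 wk. A candidate explanation that stays open is signal from sequences other than the named genes after 3 wk. Probes of olfactory receptors, genes not known for expression in liver, were higher after 3 wk than other genes of matched level by a median of 0.9 log2 units. Of 197 tested, 162 were higher than their matched genes. Only receptors that passed the background filter were tested, and a probe could pass it through 3 wk groups alone. Part of this rise may therefore come from the filter. Fewer of the 1160 receptor probes were well above background after 3 wk, 11.9% against 13.8%. A biological difference between the samples of each time was not tested.

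Probes of 1 gene often moved apart at 8 mg/kg/day after 18 h. Over 3454 genes with several kept probes, the change of the brightest correlated with that of the next at r = 0.12, and their levels at r = 0.676. Of 931 genes with 2 or more called probes, 383 had calls both ways. Differences in array signal strength are argued against as the whole cause. With a signal covariate 67.6% of 552 called pairs moved the same way, against 60.7% of 802 without it. For a technical axis shared with time in formalin, differences within pairs in this change and in the formalin change correlated at r = 0.212. That is low for a whole cause, but it lies above 0, and noise in the differences lowers it. A part played by such an axis stays open. Different annotated transcripts are argued against as the whole cause because only 62.5% of 717 called pairs with 1 shared accession moved the same way, although the share was lower, 45.9% of 85, for pairs with different accessions. Small changes near the threshold stay open: among pairs with both probes changed 2-fold or more, 86.6% moved the same way, between the bounds of 75% and 90% set before. No biological explanation was tested.

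Counts were compared with those of 100 splits of the same arrays into groups of the same sizes, the real one included. For 8 mg/kg/day no other split gave as many calls, after 18 h (10173 calls, highest other 8960, 1 split as large) or after 3 wk (61, highest other 3, 1). With 100 splits, drawn without regard to slide, this makes chance unlikely but cannot exclude it. The count after 3 wk was 0 without slides 7 and 8. For 4 mg/kg/day chance is also unlikely and cannot be excluded, and other splits gave more calls than the real one. The counts were 282 after 18 h (highest other 801, 3 splits as large) and 122 after 3 wk (highest other 452, 2). Without slides 7 and 8 they were 107 and 0. No other split reached the count of the trend after 18 h (12154, highest other 17, 1) or 3 wk (460, highest other 149, 1). Without slides 7 and 8 the 3 wk trend had 11 calls. The formalin times (24424, highest other 10929, 1) also had no other split as large. For the difference between times (1881, highest other 1703, 1) the splits shuffled dose within each time. They thus presume no furan effect at either time and cannot test whether the effect differs. That count was 117 without slides 7 and 8 and 0 with replicate number as a block with slide. At 1 mg/kg/day (0 calls in limma at both times, with 773 and 1037 genes at an unadjusted p under 0.05; highest other 0 and 1217) and 2 mg/kg/day (0 calls, with 1471 and 2440; highest other 1 at both) all 100 splits are as large whatever the data, so this comparison says nothing there. The split with 1217 calls points to a structure of the samples. It put the 2 arrays of slides 7 and 8 together in the group without dose, and whether these slides gave the calls was not tested. The number of lists called at 8 mg/kg/day cannot be told from chance: 8 after 18 h, with 26 splits as large and 12 the highest other, and 10 after 3 wk, with 5 and 12. The median of the other splits was 5 lists after 18 h and 2 after 3 wk.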

How the results depend on the processing

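Leaving out slides 7 and 8, choosing the probe on the 18 h arrays, the signal covariate and leaving out arrays with high pancreatic marker scores were chosen only after the results were seen. The cause of the changes below was not tested, except that leaving out arrays or adding untested probes changes what is measured.

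Within 1.5 times their reported count under every alternative with all arrays were the trend after 18 h and, except for all 50 arrays in 1 fit (5400), 8 mg/kg/day after 18 h. The comparison of formalin times gave 41262 without a filter, 24320 with replicate number as a block and 18445 in vehicle arrays only. At 1 mg/kg/day the count was 0 in limma throughout, with 773 and 1037 genes at an unadjusted p under 0.05 in the reported analysis.

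At 2 mg/kg/day after 18 h, 1 gene was called with normexp background and 2 each with no slide block, slide as a random block and the series matrix; after 3 wk, 284 with all 50 arrays in 1 fit. At 4 mg/kg/day after 18 h the count fell to 57 with no filter, 52 with no slide block, 35 with all 50 arrays in 1 fit and 107 without slides 7 and 8. After 3 wk it was 276 with quantile normalization, 579 with the percentile over detected probes, 193 with normexp, 17 with no filter, 35 with no slide block, 427 with a random block, 190 with scan date, 217 with the series matrix, 1762 with all 50 arrays in 1 fit and 0 without slides 7 and 8. For 8 mg/kg/day after 3 wk the same settings gave 172, 239, 113, 22, 362, 714, 119, 198, 1438 and 0, and the signal covariate 25. Leaving out these slides left 2 dosed arrays of 8 mg/kg/day. The trend after 3 wk was 62 with no filter, 1945 with no slide block, 1739 with a random block and 11 without slides 7 and 8. The difference between formalin times had 3193 calls with normexp, 1145 with no filter, 3659 with the series matrix and 117 without slides 7 and 8. With replicate number as a block with slide it had 0 (4062 at an unadjusted p under 0.05). Of 25 pairs of arrays with 1 replicate number, 14 correlated over 0.1, and 5 with slide removed. In the group, 12 and 4 of 25 correlated best with their own number. Many of these pairs lay on 1 slide, such as those of replicates 1, 4, 12 and 31. A shared slide can raise their correlation, and removing slide can lower it. These counts therefore do not show whether the animals were the same. The correlation between times was 0.393 with no slide block, 0.319 with a random block, 0.0936 with the series matrix and 0.422 without slides 7 and 8. With an estimated correlation 1 list was called at 8 mg/kg/day after 18 h and 2 after 3 wk.

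With single arrays left out, counts ranged from 43 (4 mg/kg/day replicate 35) to 509 (replicate 31) at 4 mg/kg/day and from 6753 to 11207 (vehicle replicates 2 and 4) at 8 mg/kg/day after 18 h. After 3 wk they ranged from 1 (4 mg/kg/day replicate 34) to 361 (vehicle replicate 3) and from 16 (vehicle replicate 1) to 222 (8 mg/kg/day replicate 45). The trend after 3 wk ranged from 43 (8 mg/kg/day replicate 43) to 766 (1 mg/kg/day replicate 11), and 17 of 25 arrays moved it over 1.5 times. The difference between times ranged from 968 (8 mg/kg/day replicate 44 of 3 wk) to 2445 (vehicle replicate 1 of 3 wk), and the correlation from -0.00263 to 0.408 (vehicle replicates 1 and 3 of 3 wk).

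Signs reversed most often with the probe chosen on the 18 h arrays: Ets1 0.273 at 4 mg/kg/day and Rpl27 -0.194 at 8 mg/kg/day and -0.0337 in the trend, after 18 h; Cdkn1a 2.82 at 4 mg/kg/day, 3.29 at 8 mg/kg/day and 0.449 in the trend, with Mki67 0.229 in the trend, after 3 wk, where these probes were well above background on 0 of 5 vehicle arrays, so that only their direction counts. Between formalin times this probe gave Cdkn1a -2.47, Hmox1 -2.47, Gstm1 -2.88, Bhlhe41 -1.31, Adad1 -0.418 and Mki67 -0.334. Quantile normalization gave Ahsg -0.0277, Cyp2e1 -1.06 and Mt1 -0.526, the series matrix Cyp2e1 -0.0588, vehicle arrays only Gsta2 -0.413, and normexp Nqo1 0.205, Elane 0.31, Krt19 0.519 and Ccng1 0.167. Of the 1872 values of named genes at 8 mg/kg/day after 18 h under other settings, 1757 kept direction and side of the threshold, and of 1620 after 3 wk, 1455.

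The split of calls moved with scaling. Over detected probes 8 mg/kg/day gave 3890 higher and 6818 lower after 18 h, and 56 and 183 after 3 wk, where the median of all genes moved by -0.19 and -0.12. At 4 mg/kg/day after 18 h the splits were 98 and 141, and with the series matrix 115 and 177. Between formalin times the median moved by -0.16 with quantile normalization, -0.25 over detected probes, 0.28 with normexp and 0.62 with no filter. Signal over background limits the 3 wk comparisons: 45.4% of probes were well above background, against 57.4%.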

Other observations

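Apart from the second detection flag, which was planned, the values in this part were looked at only after the results were seen.

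The first component of all genes held 40.7% of the variance among 18 h arrays and 28.6% among 3 wk arrays, and the second 15.1% and 10.9%. On the first component every 3 wk array of slides 7 and 8 scored from 43.3 to 117, and no other 3 wk array above 7.32. Among the arrays on these slides were 8 mg/kg/day replicates 41, 43 and 44, but only replicate 3 of vehicle. The correlation of arrays on 1 slide was 0.348 after 18 h and 0.233 after 3 wk.

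Both detection flags of the scanner moved the same way. The share of probes positive and significant over background differed by -8.57 percentage points after 3 wk (two-sided permutation test, n = 25 arrays per time, p = 1e-05, the smallest value the resamples can give), and the share well above background was lower in 24 of 25 pairs of arrays with the same dose and replicate number.

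In 8 mg/kg/day replicate 45 of 18 h, the array with high pancreatic markers, macrophage markers lay within the range of the other arrays of the group, at 0.423 against 0.176 to 0.813, as did periportal, cholangiocyte, erythroid and adipocyte markers. Pericentral hepatocyte markers lay above it, at 0.06 against -0.369 to -0.0679, as did endothelial markers, at -0.135 against -0.4 to -0.14, and T and NK cell markers lay below it, at -0.0919 against 0.00632 to 0.292.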
